A study of Zea mays with 69 samples.

How the data were processed

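RNA was measured in roots of the maize inbred line B73 in 69 libraries. Per the labels' protocols, chlorine-sterilised seedlings were grown in autoclaved calcined clay in covered, sealed pots in a greenhouse, a pooled suspension of 10 bacterial strains in dilute medium was added to the roots of 1 arm, and total RNA that included small RNA was extracted. The labels describe library construction for both messenger RNA and microRNA; the files analysed here hold 1 count per gene and library. What the untreated roots received in place of the suspension, and the hour of the day at which roots were taken, are not given in the sources used here.

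The deposited files hold counts: whole numbers of sequenced reads assigned to each feature in 1 library, with no normalisation. Reads were aligned with HISAT2, per the submitters' processing notes. The program that counted them, its strand setting, its handling of reads that match several places, the genome build and the annotation are not given in the sources used here, so no coordinates are printed, and counts of near-identical copies and of overlapping or antisense genes are uncertain. No row lacked a feature name. The 46272 features were 44146 with Zm00001d identifiers, 1798 with ENSRNA identifiers, 174 with GRMZM identifiers and 154 microRNA precursor loci.

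The reference gene table used here, from the assembly Zm-B73-REFERENCE-NAM-5.0, paired 0 of the Zm00001d, ENSRNA and GRMZM identifiers with a name and 153 of the 154 microRNA loci. The 32 gene lists fixed before the data were examined are defined by gene names and product descriptions, so they matched 0 genes, and none of their set tests could be run. Genes are therefore named by identifier only. The rule, also fixed before the data were examined, takes at most 2 identifiers higher and 2 lower per comparison, by the largest log2 fold change among genes with an adjusted p under 0.05 and a mean of at least 1 CPM (counts scaled to a common library size) in the higher arm. At a single time point all 3 libraries of one arm had to lie above all 3 of the other. In an average over several time points the sign had to be the same at each. The microRNA precursor loci, which carry names, were described as a group only after the data had been seen. No locus met the rule's minimum of 1 CPM together with its other conditions.

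Genes with low counts were removed with edgeR's filterByExpr on the 23 groups, which left 30783 features, 13 of them microRNA loci and 392 ENSRNA features. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust estimation, in a one-way design with 23 groups that share one estimate of the spread over all 69 libraries, and p-values were adjusted by the Benjamini-Hochberg method over all features tested. Unadjusted counts are of genes with an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the features tested, so these counts have to be read against that share. CPM values use the scaled library sizes and are given as mean ± SD over libraries. Log2 fold changes are inoculated minus uninoculated, with the standard error (SE) from the fit. Contrasts were taken at each of the 11 times, and as equal-weight averages over an early stretch of 30 min to 6 h, a middle stretch of 12 h to 96 h and a late stretch of 7 to 20 days. F tests asked whether any of the 11 contrasts differed from 0, whether they differed from each other, and whether the uninoculated groups changed over time. A fold against a group with 0 counts is a lower bound, computed against 3 counts over the group. With 1 to 3 counts the ratio has an exact 95% binomial interval, which covers counting error only.

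Total counts per library ran from 52818451 to 75285288. No pair of replicates looked like a single library deposited again: the chi-square per degree of freedom between replicates, over genes with a summed count of 20 or more, was 15.6 or more in all 69 pairs. A library was said to stand apart when its score on the second principal component of log2 CPM lay over 3 scaled median absolute deviations from the median. Replicate numbers are shared by the arms in the labels. Deviations of same-numbered libraries from their group means correlated at over 0.1 in every pair at 96 h alone, from 0.226 to 0.628, so the replicate block was read as a pairing at 96 h only, where a block nested in the time called 0 genes, as did the fit without it.

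The test was checked on counts simulated from the libraries' means and sizes, with 200 genes changed. Of these, 30394 genes passed the filter. In the 6 h contrast the test recovered 36% of the 2-fold changes and 81.6% of the 4-fold changes, with 10 false among 126 calls. In the late average it recovered 72% and 96.9%, with 12 false among 179 calls. At 24 h, where nothing had been changed, it called 0 genes. The simulated libraries were independent, with the same spread of a gene in every group. The check therefore does not measure false calls where libraries stand apart, genes vary together or groups differ in spread.

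The alternatives fixed beforehand were median-of-ratios size factors in the edgeR fit, no filter on low counts, a replicate block, leaving out each library in turn, DESeq2 1.42.0, limma voom with sample quality weights (limma 3.58.1), and a fit of only the libraries of one time point or stretch. Chosen after seeing the data were a replicate block nested in the time, fits without the 6 libraries that stood apart, fits without 6 h, and, for the named genes and loci, the fits of only one time point or stretch.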

Results

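Gene counts were compared between maize roots given a synthetic community of 10 bacterial strains and roots given no treatment. The roots came from the inbred line B73, the line used for the maize reference genome, and the strains belonged to the genera Acinetobacter, Arthrobacter, Bacillus, Chryseobacterium, Duganella, Flavobacterium, Microbacterium, Pedobacter, Pseudomonas and Shewanella. Uninoculated roots were taken at 0 h, and both arms were taken at 30 min, 1 h, 3 h, 6 h, 12 h, 24 h, 48 h and 96 h and at 7, 14 and 20 days, with 3 libraries in each of the 23 groups. The total count per library lay between 52818451 and 75285288. The labels do not say that the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries and not necessarily between plants. The library names in the file headers form one series from 0 h to 96 h (51 libraries) and another from 7 to 20 days (18 libraries), which cannot be separated from time, while both arms lie in both series. Genes carry identifiers that the reference gene table does not pair with names, so they are given by identifier, and only microRNA precursor loci are given by name. At each single time all 3 libraries of one arm lay above all 3 of the other for the identifiers named, because the rule required it. Among all genes called, the share with such arms ran from 36.4% at 12 h to 98.3% at 14 days. Among all tested genes it was 7.34% and 21.3% at these 2 times. Of the 52 named identifier results, 10 were called in every alternative that gave a value for them, and of the 6 calls of microRNA loci 0 were. On the second principal component 6 libraries stood apart from the rest: uninoculated 1 h replicate 3 (-5.1 scaled deviations from the median), uninoculated 6 h replicate 2 (-4.5), inoculated 12 h replicate 3 (-3.4), uninoculated 12 h replicate 2 (-5.99), inoculated 96 h replicate 1 (-3.78) and uninoculated 7 day replicate 1 (-4.53).

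At 6 h, 2266 genes were higher and 2640 were lower in inoculated roots, 15.9% of the 30783 features tested. Zm00001d007049 was counted 7272 times in inoculated roots (43.2 ± 42.8 CPM, SD, n = 3) and 0 times in uninoculated roots, at least 2280-fold higher. Its fitted log2 fold change, 14.37, ran from 11.76 to 28.15 over its alternatives, so the size is uncertain. Zm00001d039533 was also at 0 in uninoculated roots and at 11 ± 6.31 CPM (SD, n = 3) in inoculated roots, at least 591-fold higher (edgeR adjusted p = 6.66e-05 and 6.51e-06 for these 2 genes). Zm00001d029135 fell from 2.48 ± 1.45 to 0.0671 ± 0.0308 CPM, a log2 fold change of -5.14 (SE 1.16, edgeR adjusted p = 0.00156), and Zm00001d017140 fell from 1.86 ± 1.84 to 0.0664 ± 0.0422 CPM, a log2 fold change of -4.71 (SE 1.14, edgeR adjusted p = 0.00284). Of the 4906 genes that differed, 2508 did so by 2-fold or more, and 4467 (91.1%) had arms that did not overlap, where chance gives 10% of genes and 31.4% of all tested genes had such arms. The precursor locus zma-MIR159a, of a microRNA family known to target MYB transcription factors, rose from 0.0293 ± 0.0266 to 0.200 ± 0.0605 CPM (35 against 5 counts, edgeR adjusted p = 0.0072). The locus zma-MIR164d, of a family known to target NAC transcription factors, fell from 0.201 ± 0.0543 to 0.0460 ± 0.0261 CPM (8 against 33 counts, edgeR adjusted p = 0.036). The call of zma-MIR159a was lost without uninoculated replicate 2 (adjusted p = 0.0635, range over its alternatives 2.91e-05 to 0.0635), and that of zma-MIR164d in 7 of 13 alternatives (adjusted p up to 0.167). The count of genes was 1581 without inoculated replicate 1 and 2410 without uninoculated replicate 2, a library that stood apart. Without all 6 libraries that stood apart it was 4054. More genes were higher than lower in 7 alternatives, among them median-of-ratios size factors (2534 higher, 2429 lower) and the fit without uninoculated replicate 2 (1342 and 1068), without which Zm00001d017140 also lost its call (log2 fold change -3.67). The count was 1989 in a fit of the 6 libraries of this time alone and 16815 with limma voom and sample quality weights.

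**Figure D1:**
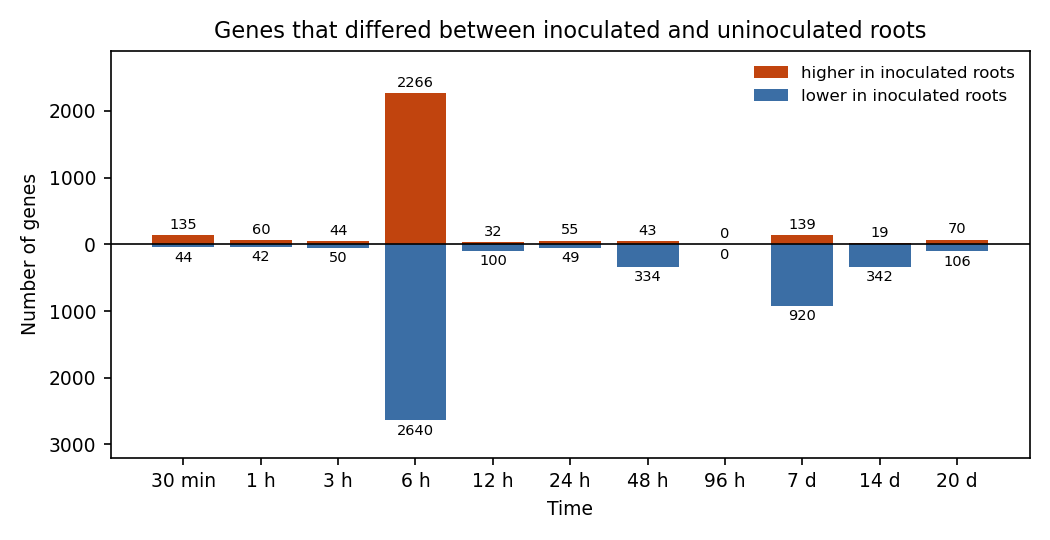
Number of genes higher (above the 0 line) and lower (below it) in inoculated than in uninoculated roots at each of the 11 times, at an edgeR adjusted p under 0.05 with 3 libraries per arm. The bars at 6 h, 2266 higher and 2640 lower, are taller than those at the other times, and at 96 h both counts are 0. Of the 106 lower at 20 days, 91 are ENSRNA features that moved by about the same amount.

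Averaged over 30 min to 6 h, 416 genes were higher and 279 lower in inoculated roots. Zm00001d047330 was at 4.47 ± 3.48 CPM in inoculated and 0.831 ± 0.682 CPM in uninoculated roots (SD, n = 12), 4.74-fold higher (log2 SE 0.41, edgeR adjusted p = 0.000842). Zm00001d044387 was at 1.56 ± 1.73 against 0.247 ± 0.395 CPM, 7.56-fold higher (log2 SE 0.75, edgeR adjusted p = 0.0226). Zm00001d024210 was lower, at 1.66 ± 1.48 against 16.5 ± 30.3 CPM, and so was Zm00001d024207, at 1.18 ± 0.993 against 10.8 ± 18.6 CPM (edgeR adjusted p = 0.0381 and 0.03). None of the 13 microRNA loci passed the test. Zm00001d044387 lost its call without either of 2 single libraries (inoculated 3 h replicates 1 and 2), Zm00001d024210 and Zm00001d024207 lost theirs without any of 15 and 9, and without uninoculated 3 h replicate 2 their log2 fold changes went from -2.68 and -2.44 to -1.94 and -1.79. Without 6 h the average over the remaining times held 198 higher and 261 lower genes, so the balance turned, as it did with limma voom and quality weights (3201 higher, 3390 lower), and DESeq2 called 1245. Of the 24 libraries, 8 moved the count by over 1.5 times when left out: to 438 and 411 (inoculated 30 min replicate 2 and 6 h replicate 1), 267 (inoculated 3 h replicate 3), 407 and 437 (uninoculated 30 min replicate 3 and 3 h replicate 1), 388 and 450 (uninoculated 1 h replicate 3 and 6 h replicate 2, which both stood apart), and 1480 (uninoculated 1 h replicate 1). A fit of these times alone called 182, without Zm00001d024210 and Zm00001d024207.

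At 30 min, 135 genes were higher and 44 lower. Zm00001d031796 was at 5.15 ± 3.49 CPM in inoculated and 0.0605 ± 0.0497 CPM in uninoculated roots, a log2 fold change of 6.36 (SE 1.41, edgeR adjusted p = 0.0181), and Zm00001d044387 was at 1.88 ± 0.932 against 0.0222 ± 0.0103 CPM (6.29, SE 1.55, edgeR adjusted p = 0.0351). Zm00001d002545 fell from 12.0 ± 6.35 to 1.69 ± 0.441 CPM and Zm00001d026017 from 14.2 ± 9.58 to 2.07 ± 0.471 CPM (edgeR adjusted p = 7.42e-05 and 0.000147). The locus zma-MIR156b, of a family known to target SBP-box transcription factors, was at 0.168 ± 0.075 against 0.0440 ± 0.0249 CPM, which did not pass over all features (edgeR adjusted p = 0.158) and passed over the 13 loci alone (adjusted p = 0.0397), a group chosen after the data were seen. Zm00001d031796 and Zm00001d044387 each lost their call without any of 5 single libraries. Without inoculated replicates 1, 2 and 3 in turn the counts were 52, 44 and 107, and without uninoculated replicates 1, 2 and 3 they were 174, 15 and 14. A fit of the 6 libraries of this time alone called 735 higher and 375 lower genes. Limma voom with quality weights called 2727 higher and 2202 lower, and DESeq2 called 271 and 108. The fit without the libraries that stood apart called 392 and 268.

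At 1 h, 60 genes were higher and 42 lower. Zm00001d024522 rose from 2.81 ± 0.943 to 51.4 ± 21.6 CPM and Zm00001d025141 from 0.652 ± 0.589 to 13.2 ± 9.40 CPM, 18.4-fold and 21.2-fold (edgeR adjusted p = 0.00438 and 0.00751). Zm00001d017801 fell from 15.3 ± 17.1 to 0.304 ± 0.208 CPM and Zm00001d030513 from 1.15 ± 1.65 to 0.0788 ± 0.0163 CPM (edgeR adjusted p = 0.0152 and 0.0348). At 3 h, 44 genes were higher and 50 lower. Zm00001d014494 was at 5.15 ± 8.73 against 0.0318 ± 0.0153 CPM (edgeR adjusted p = 0.0198). Zm00001d036450 had 262 counts in inoculated and 2 in uninoculated roots, a ratio whose counting interval ran from 36.9 to 1120 (edgeR adjusted p = 0.0456). Zm00001d046137 had 0 counts in inoculated and 306 in uninoculated roots, at least 99.3-fold lower, and Zm00001d027695 fell from 2.96 ± 2.63 to 0.0488 ± 0.0845 CPM (edgeR adjusted p = 0.00279 and 0.0107). Without inoculated 3 h replicate 3, the fitted log2 fold changes of Zm00001d014494 and Zm00001d036450 went from 7.24 and 6.83 to 1.76 and 1.44, and without uninoculated 1 h replicate 3, which stood apart, that of Zm00001d030513 went from -3.74 to -1.27, with the calls lost. Without uninoculated 3 h replicate 1 Zm00001d046137 and Zm00001d027695 lost their calls, and their fitted log2 fold changes went from -9.64 and -5.85 to -7.69 and -4.97. For Zm00001d027695 either of 2 single libraries ended the call. For Zm00001d017801 any of 4 did, and its log2 fold change went from -5.69 to -4.18 without uninoculated 1 h replicate 1. Without inoculated 1 h replicate 1 that of Zm00001d025141 went from 4.41 to 3.67 and its call was lost. Zm00001d024522 was called in every alternative except the fit of the 1 h libraries alone. DESeq2 turned the balance at both times, to 105 higher and 122 lower at 1 h and 98 and 59 at 3 h. It also turned at 1 h without uninoculated replicate 1 (53 and 73) or 2 (113 and 133). At 3 h it turned with limma voom and quality weights (396 and 376) and without inoculated replicate 1 (82 and 39) or 2 (127 and 32). Fits of the 6 libraries of either time alone with edgeR called 0 genes, where DESeq2 on all libraries called 227 at 1 h and 157 at 3 h, limma voom with quality weights called 614 and 772, and the unadjusted counts of the edgeR fit of all libraries were 3180 and 1989. Without inoculated replicates 1, 2 and 3 and uninoculated replicates 1, 2 and 3 in turn, the counts were 22, 66, 52, 126, 246 and 51 at 1 h. At 3 h they were 159 and 7 without inoculated replicates 2 and 3, and 0, 207 and 33 without uninoculated replicates 1, 2 and 3.

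Averaged over 12 h to 96 h, 140 genes were higher and 293 lower in inoculated roots. Zm00001d041959 was at 29.2 ± 32.7 CPM in inoculated and 6.10 ± 9.30 CPM in uninoculated roots (SD, n = 12), 6.24-fold higher (log2 SE 0.54, edgeR adjusted p = 0.00828), and Zm00001d038696 was at 2.22 ± 2.30 against 0.330 ± 0.293 CPM, 6.01-fold higher (log2 SE 0.54, edgeR adjusted p = 0.0101). Zm00001d039116 was lower, at 1.25 ± 1.79 against 6.67 ± 7.92 CPM, as was Zm00001d035069, at 0.125 ± 0.113 against 2.21 ± 5.79 CPM (edgeR adjusted p = 0.00388 and 0.0313). The locus zma-MIR528a was higher, at 0.549 ± 0.682 against 0.159 ± 0.407 CPM (edgeR adjusted p = 0.0304). No fold is given for it, since its uninoculated libraries of 24 h had 0 counts against 63 in the inoculated ones. Together with zma-MIR408b, at 2.65 ± 3.19 against 0.937 ± 1.77 CPM (edgeR adjusted p = 0.0688), it belongs to microRNA families known to respond to copper supply. The loci zma-MIR399j (0.481 ± 0.621 against 1.70 ± 2.38 CPM, edgeR adjusted p = 0.0825) and zma-MIR399e (0.240 ± 0.155 against 0.503 ± 0.408 CPM, edgeR adjusted p = 0.119) belong to a family known to accumulate under phosphate shortage. Adjusted over the 13 loci alone, these 4 passed, 2 higher and 2 lower. Without inoculated 96 h replicate 1, a library that stood apart, the count of genes was 173 and zma-MIR528a had an adjusted p of 0.768 (range over its alternatives 0.00218 to 0.768). Without that library Zm00001d041959 and Zm00001d038696 also lost their calls (log2 fold changes from 2.64 and 2.59 to 1.87 and 2.29), and without uninoculated 12 h replicate 2 that of Zm00001d035069 went from -2.88 to -1.61 and was not called. In a fit of these times alone, of the 4 identifiers, Zm00001d038696 was called and the others were not. Of the 24 libraries, 9 others moved the count by over 1.5 times: uninoculated 48 h replicate 3 (to 833) and 12 h replicate 3 (to 720), inoculated 12 h replicate 1 (263), 24 h replicate 1 (227) and 48 h replicate 3 (196), and uninoculated 24 h replicates 1 and 2 (252 and 240), 48 h replicate 1 (254) and 96 h replicate 1 (271).

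**Figure D2:**
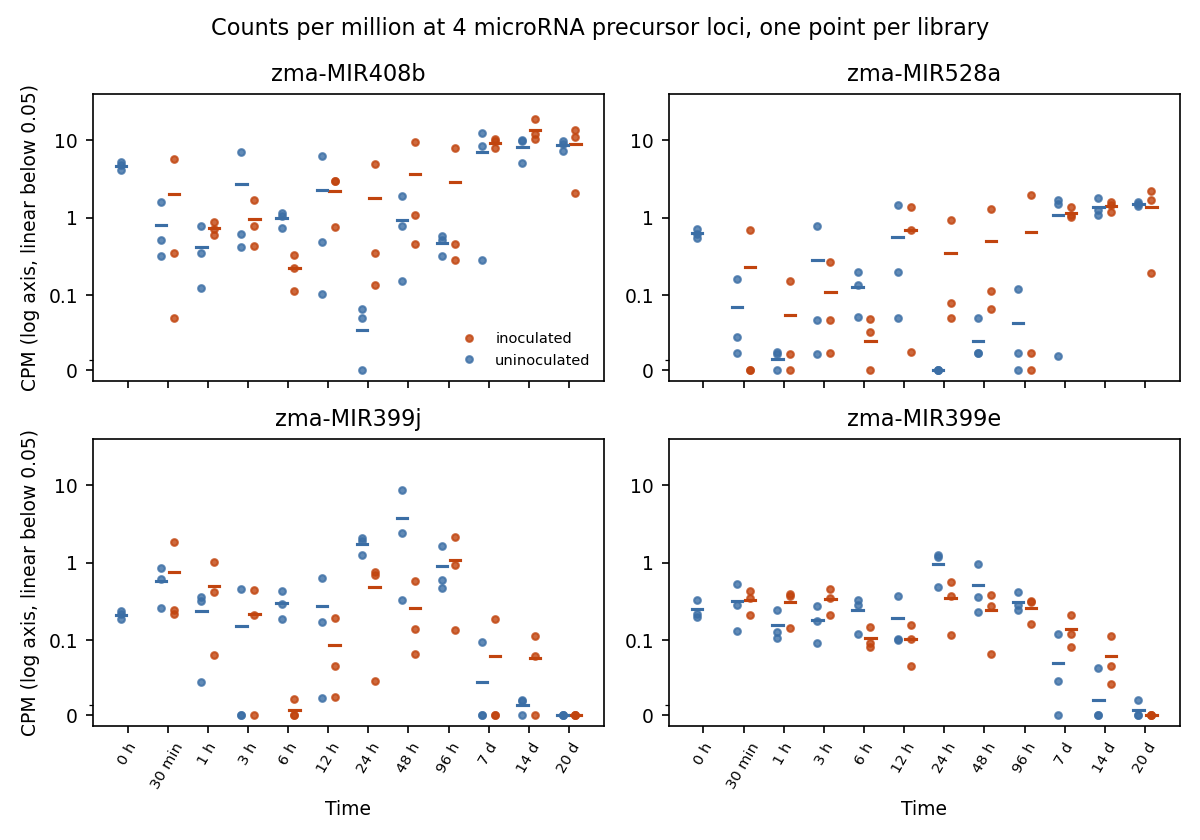
CPM at 4 microRNA precursor loci by time, on an axis that is logarithmic above 0.05 and linear below it, with one point per library and a short line at each group's mean of 3 libraries (red, inoculated; blue, uninoculated). Libraries of one group spread widely at zma-MIR408b, as at 48 h in inoculated roots (0.461 to 9.34 CPM), while zma-MIR399j is at 0 CPM in the 6 libraries of 20 days.

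At 12 h, 32 genes were higher and 100 lower. Zm00001d029038 rose from 0.833 ± 0.318 to 8.20 ± 4.04 CPM and Zm00001d004894 from 0.136 ± 0.106 to 1.39 ± 0.631 CPM (edgeR adjusted p = 0.0027 and 7.08e-05). Zm00001d015986 had 1 count in inoculated and 887 in uninoculated roots, a ratio with a counting interval of 171 to 37800 (edgeR adjusted p = 2.01e-05), and Zm00001d041657 was at 4.12 ± 2.41 against 53.6 ± 76.8 CPM (edgeR adjusted p = 0.0174). The direction rested on uninoculated replicate 2, which stood apart: without it the fitted log2 fold changes of Zm00001d015986 and Zm00001d041657 went from -9.67 and -3.70 to -3.35 and -1.19 with the calls lost, and 22 genes were higher and 1 lower. Limma voom with quality weights called 129 higher and 17 lower, and a fit of the 6 libraries alone called 0 (unadjusted count of the fit of all libraries 2208, DESeq2 116). Without inoculated replicates 1, 2 and 3, the last of which stood apart, the counts were 71, 75 and 156, and without uninoculated replicates 1 and 3 they were 430 and 399. At 24 h, 55 genes were higher and 49 lower. Zm00001d052532 was at 58.6 ± 63.5 against 2.81 ± 0.136 CPM and Zm00001d011847 at 15.6 ± 9.68 against 0.180 ± 0.108 CPM, both higher (edgeR adjusted p = 0.00301 and 0.0135). Zm00001d053916 fell from 5.72 ± 3.91 to 0.590 ± 0.680 CPM and Zm00001d019951 from 1.19 ± 0.421 to 0.13 ± 0.152 CPM (edgeR adjusted p = 0.0325 and 0.023). Adjusted over the 13 microRNA loci alone, 3 passed at 24 h and none did over all features: zma-MIR171f (0.33 ± 0.118 against 0.874 ± 0.562 CPM, edgeR adjusted p = 0.0146 over the loci and 0.156 over all features), zma-MIR399e (0.349 ± 0.222 against 0.979 ± 0.433 CPM, 0.0146 and 0.18) and zma-MIR408b (1.82 ± 2.73 against 0.039 ± 0.0347 CPM, 0.0455 and 0.34). Of the 326 counts of zma-MIR408b in inoculated roots at 24 h, 296 were in replicate 3 (4.97 CPM, against 0.136 and 0.354 in the others). The 4 identifiers named at 24 h each lost their call without any of 3 to 5 single libraries. Without inoculated replicate 1 the log2 fold changes of Zm00001d052532, Zm00001d011847 and Zm00001d019951 went from 4.38, 6.42 and -3.15 to 3.00, 5.82 and -2.71. Without uninoculated replicate 2 that of Zm00001d053916 went from -3.25 to -2.62. The balance at 24 h turned in 7 alternatives, as with limma voom and quality weights (167 higher, 479 lower). Without inoculated replicates 1, 2 and 3 and uninoculated replicates 1, 2 and 3 in turn the 24 h counts were 10, 155, 149, 6, 2 and 31, and a fit of the 6 libraries alone called 0 (unadjusted count of the fit of all libraries 2530, DESeq2 257, limma voom with quality weights 646).

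At 48 h, 43 genes were higher and 334 lower. Zm00001d047658 rose from 1.31 ± 1.54 to 59.4 ± 41.5 CPM (edgeR adjusted p = 0.0297). Zm00001d004671 had 711 counts in inoculated and 3 in uninoculated roots, a ratio with a counting interval of 79 to 1130 (edgeR adjusted p = 0.0177). Zm00001d032371 was lower, at 0.0835 ± 0.00373 against 7.94 ± 13.5 CPM, and Zm00001d015986, also lower at 12 h, was at 0.0221 ± 0.00877 against 4.08 ± 6.98 CPM (edgeR adjusted p = 1.57e-06 and 8.29e-05). The locus zma-MIR399j fell from 3.84 ± 4.41 to 0.262 ± 0.277 CPM (log2 fold change -3.84, SE 0.86, edgeR adjusted p = 0.00886). Without uninoculated replicate 1 the log2 fold changes of Zm00001d032371 and Zm00001d015986 went from -6.54 and -7.39 to -0.84 and -1.11 with the calls lost, and Zm00001d047658 and Zm00001d004671 were not called either. The 48 h count was then 0 and zma-MIR399j had an adjusted p of 0.663 (range over its alternatives 0.000257 to 0.663), and without the other uninoculated replicates, 2 and 3, the counts were 745 and 996. Without inoculated replicates 1, 2 and 3 they were 200, 445 and 182, and limma voom with quality weights and a fit of the 6 libraries alone each called 1 gene. At 96 h edgeR called 0 genes, DESeq2 called 5 and limma voom with quality weights called 338. In the edgeR fit 515 genes had an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the 30783 features tested, which is more than 515. The unadjusted count at 96 h is therefore no sign of differences that the adjustment hid. A count below that share cannot show that there were none either. Of all tested genes 4.79% had arms that did not overlap at 96 h, where chance gives 10%.

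Averaged over 7 to 20 days, 56 genes were higher and 641 lower in inoculated roots, so that 92.0% of these genes were lower (84.8% without uninoculated 7 day replicate 1, which stood apart). Zm00001d020340 was at 20.4 ± 14.4 CPM in inoculated and 6.45 ± 6.29 CPM in uninoculated roots (SD, n = 9), 3.30-fold higher (log2 SE 0.40, edgeR adjusted p = 0.00891), and Zm00001d023781 was at 1.09 ± 0.383 against 0.437 ± 0.368 CPM, 2.93-fold higher (log2 SE 0.24, edgeR adjusted p = 4.9e-05). Zm00001d019758 was lower, at 0.653 ± 0.703 against 7.50 ± 15.8 CPM, and Zm00001d023017 was lower, at 0.16 ± 0.119 against 1.04 ± 0.866 CPM (edgeR adjusted p = 4.1e-05 and 9.71e-05). Without uninoculated 7 day replicate 3 the log2 fold change of Zm00001d019758 went from -3.19 to -0.81 and its call was lost. In a fit of the late libraries alone Zm00001d023781 was called, and Zm00001d020340, Zm00001d019758 and Zm00001d023017 were not. The locus zma-MIR156b was at 0.233 ± 0.0618 against 0.163 ± 0.0997 CPM, which passed over the 13 loci alone (adjusted p = 0.0396) and not over all features (edgeR adjusted p = 0.0912). The count was 380 without inoculated 14 day replicate 1 and 1393 without uninoculated 7 day replicate 2, and it was 323 in a fit of the late libraries alone.

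At 7 days, 139 genes were higher and 920 lower. Zm00001d044117 rose from 0.0958 ± 0.0569 to 1.11 ± 0.360 CPM and Zm00001d004243 from 0.253 ± 0.196 to 1.06 ± 0.180 CPM (edgeR adjusted p = 0.0417 and 0.0193). Zm00001d035080 was lower, at 0.0919 ± 0.103 against 4.32 ± 5.58 CPM (edgeR adjusted p = 0.00092), and Zm00001d031728 had 1 count against 247, a ratio with a counting interval of 54.2 to 12100 (edgeR adjusted p = 0.00876). Without uninoculated replicate 3 the fitted log2 fold changes of Zm00001d035080 and Zm00001d031728 went from -5.56 and -7.57 to -3.49 and -3.90 with the calls lost, and Zm00001d044117 lost its call without any of 6 single libraries and Zm00001d004243 without any of 3. The loci zma-MIR156b, at 0.232 ± 0.0122 against 0.0594 ± 0.0543 CPM, and zma-MIR164b, at 0.661 ± 0.125 against 0.257 ± 0.0803 CPM, were higher (edgeR adjusted p = 0.0164 and 0.0215). Each of these 2 calls was lost when any of several single libraries was left out, with adjusted p up to 0.549 and 0.823 over the alternatives. Without inoculated replicates 1, 2 and 3 and uninoculated replicates 1, 2 and 3 in turn the counts of genes were 388, 351, 280, 662, 3266 and 620, and uninoculated replicate 1 (662) stood apart. Limma voom with quality weights called 11, DESeq2 1354 and a fit of the 6 libraries alone 0 (unadjusted count of the fit of all libraries 5161). The mean squared deviation of log2 CPM from the group mean was 0.299 to 0.572 in the uninoculated 7 day libraries. In the inoculated ones it was 0.0746 to 0.0836, a contrast that the spread shared by all groups leaves out.

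At 14 days, 19 genes were higher and 342 lower. Zm00001d023781, higher over the late average, rose from 0.229 ± 0.0539 to 1.11 ± 0.168 CPM at 14 days, and Zm00001d016237 was at 15.9 ± 21.1 against 1.59 ± 0.522 CPM (edgeR adjusted p = 0.00213 and 0.0157). Zm00001d006169 fell from 13.3 ± 10.1 to 0.791 ± 0.101 CPM and Zm00001d002618 from 10.8 ± 13.1 to 0.541 ± 0.498 CPM (edgeR adjusted p = 0.00125 and 0.00401). Without inoculated replicate 1 the log2 fold change of Zm00001d016237 went from 3.32 to 1.24, and without uninoculated replicate 3 that of Zm00001d002618 went from -4.34 to -2.60, with the calls lost. The count was 62 and 156 without inoculated replicates 1 and 2, 129 without uninoculated replicate 3, 827 in a fit of the 6 libraries alone and 1782 with limma voom and quality weights.

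At 20 days, 70 features were higher and 106 lower, the lower ones mostly ENSRNA features. Zm00001d041960 rose from 3.83 ± 0.577 to 36.4 ± 11.2 CPM, 9.49-fold (log2 SE 0.33, edgeR adjusted p = 2.55e-09), and was called in all 14 alternatives run for it. Zm00001d045321 was at 2.14 ± 2.83 against 0.217 ± 0.106 CPM (edgeR adjusted p = 3.29e-05). Zm00001d039314 fell from 1.20 ± 0.0364 to 0.289 ± 0.258 CPM and Zm00001d049525 from 1.21 ± 0.481 to 0.313 ± 0.143 CPM (edgeR adjusted p = 0.024 and 0.0495). Of the 176 features, 91 were ENSRNA features, all lower, with a median log2 fold change of -1.47 and quartiles of -1.49 and -1.44. With so narrow a range they moved by about the same amount and are not 91 separate results. These features hold 97.9% of the ENSRNA counts of uninoculated roots at 20 days. ENSRNA features took 2.38% ± 0.287 of all counts in uninoculated and 0.882% ± 0.147 in inoculated roots (SD, n = 3), a difference with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow (adjusted over 11 times, 0.367). The remaining 85 features were 70 higher and 15 lower. Without inoculated replicate 1 the log2 fold change of Zm00001d045321 went from 3.32 to 1.25 and its call was lost, and Zm00001d039314 and Zm00001d049525 lost their calls without any of 5 and 4 single libraries. The count was 78 without inoculated replicate 1 (12 higher, 66 lower) and 85 in a fit of the 6 libraries alone (6 higher, 79 lower). The balance turned without inoculated replicate 3 (177 higher, 129 lower) and replicate 2 (99 higher, 80 lower).

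**Figure D3:**
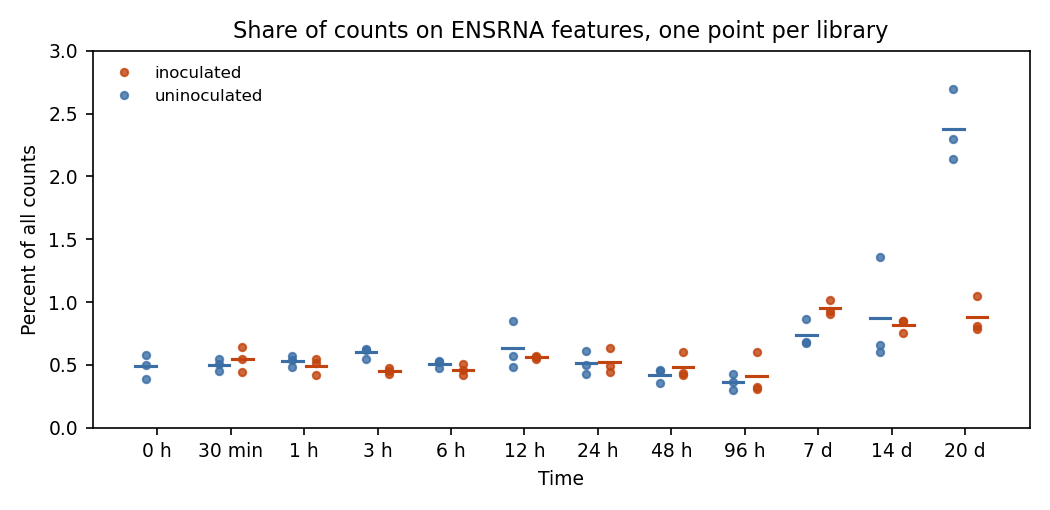
Share of all counts that fell on ENSRNA features, in percent, by time, with one point per library and a short line at each group's mean of 3 libraries. The 3 uninoculated libraries of 20 days lie at 2.14% to 2.70%, above the 66 others, of which the highest is at 1.36%.

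Over the whole course, 4086 genes had an inoculation effect at some time (13.3% of those tested), and the effect differed between times for 3134. Zm00001d041960 was one of them (edgeR adjusted p of the difference 4.11e-11): it was lower in inoculated roots at 7 days, at 8.73 ± 1.39 against 35.3 ± 17.9 CPM, and higher at 14 days, at 27.7 ± 7.63 against 5.98 ± 1.47 CPM (edgeR adjusted p = 8.84e-05 and 4.18e-05). None of the 13 microRNA loci passed the test of a difference between times. Within the libraries of 0 h to 96 h, 3490 genes had an effect at some time and for 2366 it differed between times. Within those of 7 to 20 days the counts were 1181 and 296. Without 6 h, 1786 genes had an effect at some time and 1494 differed between times. Leaving out replicate 1, 2 or 3 of every group gave 325, 328 and 1939 genes with an effect at some time and 188, 187 and 1573 that differed between times. The late average exceeded the early average for 215 genes and lay below it for 718, a comparison that also sets the 2 series of libraries against each other.

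In uninoculated roots alone, 21768 genes (70.7%) changed over the course. The number that differed from 0 h was between 256 at 96 h and 2817 at 12 h up to 96 h, and it was 13953 at 7 days, 11332 at 14 days and 12212 at 20 days, where the roots of 0 h lie in the other series of libraries. Within the libraries of 0 h to 96 h 9388 genes changed over time, and within those of 7 to 20 days 898 did. The locus zma-MIR168a, of the family known to target the Argonaute gene of the microRNA pathway, was at 0.627 ± 0.189 CPM at 0 h and at 2.65 ± 2.07, 3.56 ± 0.532 and 5.59 ± 1.05 CPM at 7, 14 and 20 days, log2 fold changes of 2.13 (SE 0.36), 2.51 (SE 0.35) and 3.16 (SE 0.35) against 0 h (edgeR adjusted p = 4.74e-06, 1.53e-07 and 3.84e-10). Inoculated roots held 5.89 ± 1.98 CPM at 20 days. The phosphate-related loci zma-MIR399j and zma-MIR399e changed over time in uninoculated roots (edgeR adjusted p = 2.06e-08 and 5.31e-09). The first was at 0.215 ± 0.0251 CPM at 0 h, 1.78 ± 0.442 at 24 h and 0 in the libraries of 20 days, and the second at 0.251 ± 0.0703, 0.979 ± 0.433 and 0.00493 ± 0.00853 CPM. The locus zma-MIR408b also changed (edgeR adjusted p = 9.28e-05), and was at 4.70 ± 0.608 CPM at 0 h, 0.0390 ± 0.0347 at 24 h and 8.57 ± 1.25 at 20 days. Against 0 h its log2 fold change was -6.83 (SE 1.85, edgeR adjusted p = 0.0472) at 24 h. At 20 days it was 0.87 (SE 0.95, edgeR adjusted p = 0.496), so no rise above 0 h was called there.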

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

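Of the tests below, that of the late stretch in its own libraries and that of the held-out libraries at 6 h were chosen after the results were seen. The inoculation effect differed between times for 3134 genes, by an edgeR test of the difference itself. It differed between the early and the late average for 933 genes, by the same kind of test. Of the 49 identifiers named, 41 had an effect that differed between times, but these were picked for large effects, so their share says little about other genes.

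The first pattern weighed is the count of 4906 genes at 6 h. Genes were called from 4 of the 6 libraries and followed in the other 2, an inoculated library and uninoculated replicate 3, and the slope of the held-out on the calling difference was 0.93, 0.83 and 0.51 for inoculated replicates 1, 2 and 3. The lowest, 0.51, lay between the bounds set for this test (under 0.5 and at least 0.8), so the test cannot decide. All 3 slopes share uninoculated replicate 3, so the low one may lie with inoculated replicate 3, which did not stand apart. The count was 2410 without uninoculated replicate 2, and 4054 without all 6 libraries that stood apart. It was lower still, 1581, without inoculated replicate 1, which did not stand apart. These counts do not single out the libraries that stand apart, which stay open as part of the cause. With the second principal component as a covariate, 4118 of the 4906 genes were also called, which argues against that axis as the whole cause. However, the median absolute log2 fold change of all 4906 went from 1.03 to 0.86. The balance also turned (5849 called in all, 3156 higher and 2693 lower). A response to inoculation may be part of the pattern, but handling that differed between the arms could not be tested, and the size of the count is uncertain (1581 without inoculated replicate 1).

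The second pattern is that 92.0% of the genes of the late average were lower in inoculated roots. The share was 84.8% without uninoculated 7 day replicate 1, and 94.7% in the late libraries alone, which argues against that library and against spread borrowed from earlier times as the cause. How lopsided calls are under other splits could not be judged, since their median count was 1. No biological explanation was tested.

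Other splits of the libraries between the arms were refitted. At a single time 3 against 3 libraries make 10 splits, too few for a share under 0.05, so only the real and the highest other count are given, after the number of splits with as many genes. At 30 min 1 split gave as many (179, highest other 1), at 1 h 1 (102, 1), at 3 h 1 (94, 5), at 6 h 1 (4906, 197), at 12 h 4 (132, 285) and at 24 h 1 (104, 2). At 48 h 1 split gave as many (377, 219), at 96 h 10 (0, 0; unadjusted 515, DESeq2 5, limma voom 338), at 7 days 1 (1059, 276), at 14 days 1 (361, 1) and at 20 days 1 (176, 57). For the averages and the tests over time 60 splits were used (40 for time in uninoculated roots), and a share under 0.05 gave as many genes in each case. For the middle and late averages and an effect at some time, this argues against a chance division between the arms. The splits stand for no inoculation effect at any time. For late against early and a difference between times they therefore cannot exclude chance in how the effect varied. The 40 splits mix the 2 series of libraries, so they cannot separate time from series. For the early average 2 of 60 gave as many (695, highest other 4037), for the middle average 1 (433, 39), for the late average 1 (697, 148) and for late against early 1 (933, 737). For an effect at some time 1 of 60 gave as many (4086, 2027), and for a difference between times 1 (3134, 2440). For time in uninoculated roots 1 of 40 did (21768, 14094). The early split with 4037 genes points to a structure of the libraries other than inoculation: its groups had second principal component means of 20.6 and -59.7 at 1 h and 4.45 and -54.1 at 6 h, and the next most was 316. The real arms share part of that structure: replicate 3 of 1 h and replicate 2 of 6 h, with scores of -116.2 and -101, were both uninoculated. Leaving out either gave 388 or 450 early genes. For the early average the splits therefore cannot separate inoculation from this structure.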

How the results depend on the processing

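The alternatives that follow were chosen after seeing the data: the replicate block nested in the time, the fits without the 6 libraries that stood apart, those without 6 h and, for named genes, the fits of each result's own libraries. Over all alternatives 199 counts stayed within 1.5 times the reported one and 120 did not; of the values of named genes and loci 768 kept their call, 238 lost it and 0 reversed, and 4 had no adjusted p in DESeq2. Median-of-ratios size factors left 18 of 18 counts within 1.5 times. The counts outside follow, and the cause was not tested. Left-out libraries and fits of few libraries have fewer samples. That alone would not raise a count, as fits of own libraries did at 30 min (1110 against 179) and 14 days (827 against 361).

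Without a filter on low counts 12 h had 214 genes and 48 h 598. With the replicate block 96 h had 1. With the nested block 30 min had 113, 3 h 46, 12 h 52, 48 h 226, 7 days 489 and an effect at some time 2585. DESeq2 gave 379 at 30 min, 227 at 1 h, 157 at 3 h, 257 at 24 h, 5 at 96 h, 1245 for the early and 946 for the middle average. Limma voom with quality weights gave 4929 at 30 min, 614 at 1 h, 772 at 3 h, 16815 at 6 h, 646 at 24 h, 1 at 48 h, 338 at 96 h, 11 at 7 days, 1782 at 14 days, 6591 early, 980 middle and 2297 for late against early. Fits of each result's own libraries gave 1110 at 30 min, 0 at 1 h, 3 h, 12 h, 24 h and 7 days, 1989 at 6 h, 1 at 48 h, 827 at 14 days, 85 at 20 days, 182 early, 257 middle and 323 late. With edgeR on all libraries these times at 0 had 102, 94, 132, 104 and 1059 genes, and their unadjusted and other tools' counts stand with each time. Without the libraries that stood apart 30 min had 660, 24 h 181, 48 h 771, 96 h 2, 14 days 647, early 432 and middle 215. Without 6 h, early had 459, an effect at some time 1786 and a difference between times 1494.

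Leaving out single libraries (or, for tests over time, one replicate number) gave 14 to 174 genes at 30 min, 22 to 246 at 1 h, 0 to 207 at 3 h, 1581 to 5361 at 6 h, 23 to 430 at 12 h, 2 to 155 at 24 h, 0 to 996 at 48 h, 0 to 1 at 96 h, 280 to 3266 at 7 days, 62 to 302 at 14 days and 78 to 306 at 20 days. The ranges were 267 to 1480 early, 173 to 833 middle, 380 to 1393 late, 701 to 1360 for late against early, 325 to 1939 for an effect at some time, 187 to 1573 for a difference between times and 15799 to 17885 for time in uninoculated roots. Of these 183 counts 69 lay outside 1.5 times. Set tests of the gene lists could not be run, since the lists matched 0 genes.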

Other observations

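Of the tests here, the search for genes that follow zma-MIR408b, the pairs of consecutive identifiers, the gene off at 12 h and 96 h and the signs of the 6 h genes at other times were chosen after the results were seen. Within groups, libraries with more zma-MIR408b had more zma-MIR528a, both of families known to respond to copper: over 69 libraries, as deviations from group means, r was 0.87 and rho 0.81 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give, adjusted over 6 relations 6e-05 and 3e-05). Without the 2 farthest libraries r was 0.85, and it was 0.85 in the libraries of 0 h to 96 h and 0.97 in those of 7 to 20 days. The phosphate-related zma-MIR399e and zma-MIR399j also varied together (r 0.64, rho 0.67). Between zma-MIR408b and zma-MIR399j r was -0.44 (permutation p = 0.0121, adjusted 0.0241; rho -0.44), and -0.55 in the libraries of 0 h to 96 h. In those of 7 to 20 days r was 0.19, but zma-MIR399j had at most 13 counts and was mostly at 0, so the relation could not be tested there.

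A larger set of genes may move with zma-MIR408b: 10 features followed it at r of 0.8 or more, against at most 0 in 100 permutations within groups. Among them were Zm00001d018619 (r 0.93, 5.79 to 396 CPM) and Zm00001d041959 (r 0.90). In the middle average 10 of these 10 were higher in inoculated roots, 9 of them called. They were picked in these data for varying together, so their shared direction is not 10 separate results. Single inoculated libraries with high zma-MIR408b, as at 96 h (0.287 to 8 CPM within the group), enter both r and the difference between the arms. In the early average 4 of 10 were higher and in the late average 7 of 10, and edgeR called 0 in either. Without the libraries that stood apart, or without inoculated 96 h replicate 1, edgeR called 0 of them. All 10 stayed higher, and their median fitted log2 fold change went from 2.71 to 1.66 in either case, so the calls depend on that library while the direction did not change. These medians include zma-MIR528a, which had 0 counts in uninoculated roots at 24 h, and are no bound. The axis that separates replicates stays open as a source, since r of zma-MIR408b with the second principal component was -0.19 (SE 0.144) and -0.42 within 7 to 20 days.

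Zm00001d041960 was at most at 0.103 CPM in the 12 libraries of 12 h and 96 h, in both arms, and at 1.2 to 55.7 CPM (median 20.0) in the 57 others. It was the 1 gene with a median of at least 2 CPM there and under 1/100 of it at these times. Time profiles were compared across genes, which are not independent replicates, from 0 h to 96 h and not for the later times. Among the pairs of times compared, 12 h and 96 h had the highest r, 0.38. No explanation of this was tested.

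One hypothesis was that neighbouring identifiers share their response at 6 h. Of 18923 consecutive pairs, 390 were called in the same direction, against a mean of 248 and a highest of 305 in 1000 permutations of the calls. Reads shared between near-identical copies could also give these 390 pairs, which was not tested. A second hypothesis, that the 6 h genes kept their sign at other times, stays open, since 10 splits of the libraries are too few for a share under 0.05. At 24 h 80.7% had the same sign, and 6 of 10 splits were as far from 50% (highest other 87.0). At 48 h it was 75.9% with 2 of 10 (highest other 80.1), and at 12 h 74.7% with 1 of 10 (highest other 69.3). The share was 65.7% at 3 h and 54.2% at 7 days, and below 50% at 30 min (30.6%), 1 h (40.8%), 96 h (45.7%), 14 days (47.6%) and 20 days (42.2%). The numbers in brackets that follow are expected if calls were independent. They are the genes, among all features tested, expected to be called at both times with the same sign. They are not the same-sign number expected among the genes called at both times. Of the genes called both at 6 h and at another time, 56 of 58 had the same sign at 24 h (8.25) and 60 of 63 at 48 h (31.8). At 3 h it was 39 of 47 (7.53), at 12 h 16 of 18 (10.9) and at 30 min 23 of 41 (13.7). It was 91 of 151 at 7 days (89.1), 8 of 24 at 1 h (8.02), 5 of 51 at 14 days (30.7) and 3 of 15 at 20 days (14.2). Genes are not independent replicates, and these overlaps were not tested.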
